A study of Mus musculus with 2 samples.

How the data were processed

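Bone marrow cells of mouse femurs and tibias were freed with collagenase and dispase at 37 °C, strained, treated to lyse red blood cells and loaded on a microfluidic chip for the Singleron GEXSCOPE single-cell RNA kit, per the labels' protocols, which are the same for both libraries. There was 1 control library and 1 T1D library, grouped by the disease state in the labels. The deposited tables hold whole-number counts per gene and barcode, not normalized. Reads were demultiplexed with bcl2fastq 2.19, assigned to genes with featureCounts and used the mouse build mm9, per the submitters' processing notes. The aligner, the gene annotation, the rule that called barcodes cells and the collapse of molecular identifiers are not given in the sources used here, so the values are called counts throughout. The reference in hand is of another build, so no coordinates are given, and gene symbols are those of the tables. The tables held 25395 genes in the control library and 24831 in the T1D library, 22384 of them in both, and a gene listed in 1 table was set to 0 in the other. Of the 494 genes in the lists below, 6 were in neither table.

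Cells with at least 200 genes and at most 20% mitochondrially encoded counts were kept. This removed 77 of 12880 control barcodes and 192 of 15771 T1D barcodes. Doublets were called in each library with Scrublet as built into scanpy 1.11.5, at an expected rate of 6%. It marked 1 control and 2 T1D cells, under the 0.5% below which the caller was set to count as not having worked, so no cell was removed as a doublet. The lowest total among kept cells, 1904 and 1369 counts, and the median total, 3633 and 2757, differed between the libraries, and every share of cells carries that gap.

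Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen per library and merged, leaving out hemoglobin, mitochondrially encoded, Xist, Y-linked and antigen receptor variable genes. A nearest-neighbour graph with 15 neighbours was built on 30 principal components of both libraries together, without batch integration, and partitioned by the Leiden method at resolution 1 with igraph 0.11.9. Clusters were named from 27 marker sets fixed before the data were examined. A name needed at least 3 markers with a 2-fold excess and 50 CPM, and clusters with the markers of a pair of classes were left unnamed. The names carry the sense of "like" (B cell-like and so on), since no sorted reference was used. A class was compared within the libraries where it held at least 100 cells in both, which gave 11 classes, 5 of them with at least 500 cells in both.

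The Leiden method starts from a random order, and the partition was changed after class sizes had been seen. At first a single start was used. Class sizes were then found to differ between starts and between numerical settings of the processor libraries. These settings were fixed, further starts were surveyed, and the rule of the partition with the highest modularity of 10 starts was set down. For a time it was replaced by the start of 20 that agreed best with the others, and it was then restored as first set down. The partition used has a modularity of 0.8551 and 23 clusters. Over 20 starts the number of clusters ranged from 22 to 27, and the mean adjusted Rand index of the partition used with the others was 0.727. Whether depth parts the mature neutrophils was first tested on genes with the clusters held fixed, which does not bear on clusters, and that test was replaced by clustering thinned cells. The best-agreeing start is given among the alternatives, and the range over 20 starts stands beside the shares.

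Counts were summed per library and class and expressed as CPM of the class's own sum. The log2 ratio of T1D over control was taken with 5 CPM added to both, and fold values are plain ratios of CPM. Ratios of counts have exact conditional binomial intervals, CPM values exact Poisson intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and all covering counting error only, since cells of 1 library are not replicates. Where 1 library had 0 counts, a fold is a bound computed with 3 counts in that library's class sum, and the share of cells that a count of 0 allows is that of 3 cells. With 1 library per group no test was made and no p-value is given. The size rule was an absolute log2 ratio of at least 1, at least 50 CPM in the higher library and a counting interval that excludes 1. On simulated counts with 200 changed genes, the rule recovered 0 of 50 genes changed 1.5-fold, 12 of 50 changed 2-fold and all 50 at 3-fold and at 4-fold over all kept cells (24871 genes), and 18 of 50 at 2-fold for a class holding 4% of the counts (17225 genes). It passed 0 unchanged genes in both. These counts were drawn from the control profile with counting error alone, and the changed genes were all above the 50 CPM minimum. The simulation thus says nothing of genes that differ between animals or preparations, and the 2-fold threshold itself holds back genes changed 1.5-fold.

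Genes are named by a rule fixed before the data were examined: of those past the size rule, the 10 highest and 10 lowest over all kept cells, the 8 highest and 8 lowest in classes of at least 500 cells in both libraries, and the 3 highest and 3 lowest in classes of 100 to 499 cells. Within a class, a gene's CPM had to be at least 0.5 of its CPM over all cells of the library where it was higher. Predicted genes and antigen receptor variable genes were passed over. Members of 41 gene lists fixed beforehand may be named too. Rbm3 was chosen after the values of Cirbp and of the heat shock genes were seen and before its own. The genes counted over classes were chosen after values of theirs were seen, as were Ighg2b, Ighg2c, Ighg3, Igha and Ighm. The median of a list was taken over members with a mean of at least 10 CPM and, with at least 5 such members, set against 10000 random lists of the same size matched on expression, as a description of these libraries. Lists at or under percentile 1 or at or over percentile 99 are described for all kept cells and for the classes of at least 500 cells. In the smaller classes only some lists are given, and others past these percentiles are not described. Of 34 lists with a percentile over all kept cells, 10 were at the low end and 4 at the high end.

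Alternatives fixed beforehand were other filters on cells, Leiden resolutions of 0.5 and 2, 50 principal components, each library clustered alone, cells thinned to 1000 counts, another denominator of the shares, scaling by TMM (edgeR 4.0.16) or by the median of ratios (DESeq2 1.42.0) in R 4.3.3, scaling without hemoglobin, mitochondrial and ribosomal protein genes, 1 or 20 CPM added, other thresholds, and free RNA subtracted until hemoglobin counts reached 0. The free RNA profile was that of all kept cells, since the tables hold called cells. Added after the data were seen were the same lowest total in both libraries, removal of the 6% of cells with the highest Scrublet score, a mixed B cell and monocyte cluster counted as mature B cells, totals without ribosomal RNA, the best-agreeing start, and free RNA subtracted at the level of the plasma cell genes Jchain and Igha. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures matplotlib 3.10.9.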

Results

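Single-cell RNA sequencing libraries were made from the bone marrow of femurs and tibias of C57/BL6 mice. The control library came from marrow of mice given sodium citrate, with normal blood sugar. The T1D library came from mice given streptozotocin, a compound toxic to the insulin-producing beta cells of the pancreas, with high blood sugar. There was 1 library in each group, so no difference described here has a replicate check and no test between conditions was possible. The intervals given are exact 95% intervals, which cover counting error only. The control library held 57494166 counts over 12880 barcodes, of which 12803 were kept, with a median of 3633 counts and 1051 genes per kept cell. The T1D library held 52022458 counts over 15771 barcodes, of which 15579 were kept, with a median of 2757 counts and 803 genes. The lowest total of a kept cell was also higher in the control library. Nuclear ribosomal RNA took a median of 32.4% of a control cell's counts and 36.9% of a T1D cell's counts, nearly all of it in the feature CT010467.1.

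The series title sets out to relate the bone marrow to the loss of bone in diabetic mice, and the first comparison is which cells the marrow held. Cells of the B lineage made up a smaller share of the T1D library. Pro- or pre-B cells, which carry genes of the pre-B cell receptor and of antigen receptor recombination, numbered 1443 in the control library, 11.3% of kept cells (10.7 to 11.8%). None of the 15579 T1D cells fell in these clusters, which allows a share of up to 0.0193%. Over 20 starts of the clustering this class held 689 to 1443 control cells, 5.38 to 11.3%, and no T1D cell. The 1443 cells are thus the top of that range, which is wider than the counting interval. With mature B cells added, the B lineage without plasma cells made up 17.8% of control cells (2278 cells) and 3.49% of T1D cells (543 cells), a share 5.10-fold lower in T1D. Both pro- and pre-B clusters held control cells alone, so the genes themselves were also counted over all kept cells. Rag1, a subunit of the recombinase of antigen receptor genes, had 1615 counts in the control library and 1 in the T1D library. Its partner Rag2 had 237 and 8 counts. Vpreb1 and Igll1, which encode the surrogate light chain, had 1068 against 5 and 804 against 7 counts. Dntt, the template-independent DNA polymerase of the same step, had 1364 and 81. At least 2 of these 5 genes were found in 311 control cells, 2.43% of them (2.17 to 2.71%), of which 275 lay in the pro- or pre-B clusters, and in 1 T1D cell. After thinning to 1000 counts per cell the numbers were 139 and 0.

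The neutrophil lineage was the larger counterpart, with 5766 control cells (45.0%, 44.2 to 45.9%) and 9227 T1D cells (59.2%, 58.5 to 60.0%), a ratio of 1.32 (1.27 to 1.36). Shares are relative to all kept cells, so the lower B lineage share by itself raises the T1D share of every other class. The ratio of 1.32 is thus not separate from the lower share of B lineage cells. Mature neutrophils, which carry Retnlg and Cxcr2, made up 17.6% of control and 29.6% of T1D cells. Immature neutrophils, which carry the secondary granule genes Ngp and Ltf, made up 27.5% and 29.7%. Granulocyte-monocyte progenitors, marked by Mpo, Elane and Prtn3, made up 3.16% of control cells and 6.10% of T1D cells, a ratio of 1.93 (1.72 to 2.17). Plasmacytoid dendritic cells, the main producers of type I interferon, made up 3.96% (507 cells) and 0.661% (103 cells), a share 5.99-fold lower in T1D. Mature B cells made up 6.52% and 3.49%, macrophages or conventional dendritic cells 2.54% and 1.49%, and basophils or mast cells 1.19% and 0.847%. Erythroid cells made up 2.43% and 1.84%, and stem or multipotent progenitors, whose cluster was also led by the megakaryocyte genes Pf4 and Itga2b, 2.05% and 1.53%. T or NK cells made up 4.01% and 4.61%. The intervals of the ratio included 1 for monocytes (8.77% and 8.57%), plasma cells (0.555% and 0.584%) and the small stromal or endothelial class (18 and 13 cells). Classes are named by marker genes, and clusters left without a name held 1072 control cells (8.37%) and 1709 T1D cells.

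The border between neighbouring classes depended on the start of the clustering. Over 20 starts the log2 ratio of the share stayed between -2.36 and -2.34 for the B lineage and between 0.35 and 0.40 for the neutrophil lineage. It ranged from 0.30 to 0.97 for mature neutrophils, from -0.17 to 0.50 for immature neutrophils, from -0.12 to 0.81 for monocytes, from -1.83 to -0.90 for mature B cells, and from -2.59 to -0.048 for macrophages or dendritic cells. It ranged from 0.50 to 0.97 for granulocyte-monocyte progenitors, and from -0.51 to 0.016 for stem or multipotent progenitors, a class found in 19 of the starts. When both libraries were held to the lowest total of the control library, the neutrophil lineage stayed higher in T1D at a log2 ratio of 0.28. There the mature neutrophil share was at -0.095 and the immature share at 0.58. At a Leiden resolution of 2 the immature neutrophil share was at -0.22. With at most 10% mitochondrial counts the shares were at 0.67 for erythroid cells, 0.035 for stem or multipotent progenitors and 0.038 for macrophages or dendritic cells, all in the other direction.

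**Figure D1:**
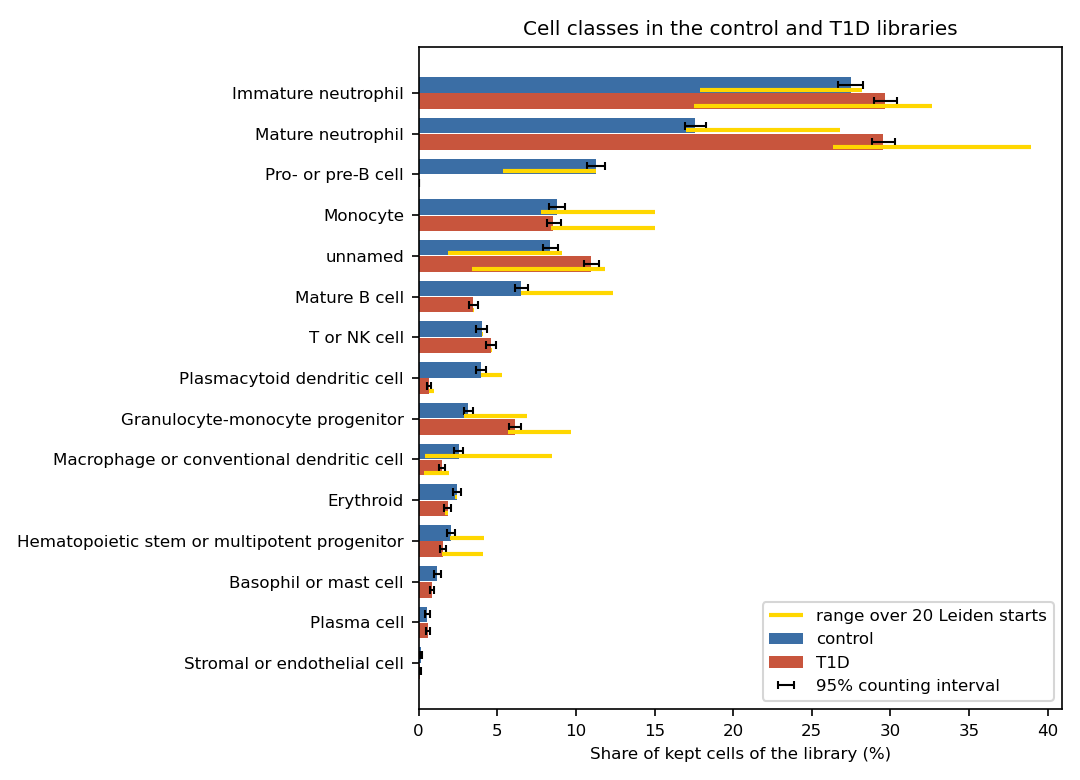
Share of kept cells in each named class, in percent, for the control and the T1D library, with exact 95% binomial intervals that cover counting error only and gold lines for the range over 20 clustering starts. Pro- or pre-B cells made up 11.3% of control cells and none of the T1D cells, and plasmacytoid dendritic cells 3.96% and 0.661%.

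The next comparison is which genes differed over all kept cells. B lineage genes made up most of those furthest below the control. Vpreb3, which takes part in pre-B cell receptor assembly, stood at 140 CPM (counts scaled to the library sum) in the control library and 2.83 in the T1D library, 49.6-fold lower (42.1 to 58.8). Akap12, a scaffold of protein kinase A, was 88.7-fold lower (64.0 to 127). The transcription factor Ebf1, which specifies the B lineage, stood at 89.5 and 8.17 CPM, and Cd79a and Cd79b, the signalling chains of the B cell receptor, were 10.2-fold and 7.93-fold lower. Fcrla, Ly6d, Bach2 and Irf4, all used in B lymphoid cells, were between 8.83-fold and 21.5-fold lower. Ifi27l2a, an interferon-induced gene, was 11.5-fold lower (10.5 to 12.7).

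Among the genes higher in T1D, Ighg1, the constant region of the IgG1 heavy chain, had 2 control and 7368 T1D counts. Plasma cells held 88.6% of the T1D counts, in 14 of 91 cells, and 1 cell held 1802 of them, so this value rests on few cells. Most others were neutrophil and myeloid genes. Asprv1, an aspartic protease, was 7.31-fold higher (6.92 to 7.72), the stefin genes Stfa1 and Stfa2l1, inhibitors of cysteine proteases, 7.57-fold and 2.54-fold, and BC100530 19.9-fold higher (17.0 to 23.4). Prok2, a chemokine-like secreted protein, was 4.09-fold higher, Pla2g7, which breaks down platelet-activating factor, 3.35-fold, and Vcan, a large proteoglycan, stood at 59.2 and 148 CPM. Cebpb, a transcription factor of myeloid differentiation, was 3.15-fold higher (3.04 to 3.26). The linker histone gene H1f0, which was higher in each of the 11 classes compared, was 4.14-fold higher (3.92 to 4.36). In all, 26 genes passed the size rule above the control and 71 below it. The rule asks for a 2-fold difference and 50 CPM, and describes these 2 libraries. The split was 34 and 45 with TMM scaling, which moved the median of all genes by 0.12 on the log2 scale, and 31 and 53 with DESeq2 scaling.

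**Figure D2:**
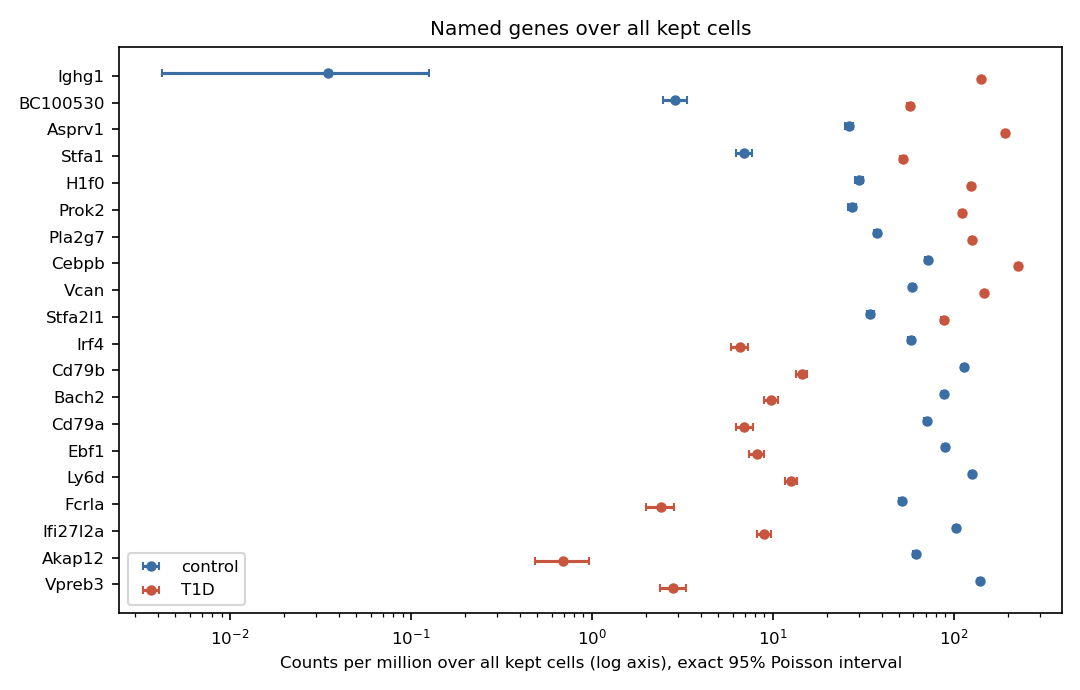
CPM over all kept cells of the 20 genes named by the size rule, on a log axis, for the control and the T1D library, with exact 95% Poisson intervals that cover counting error only. The genes named as lower in T1D include Vpreb3 at 140 CPM in control and 2.83 CPM in T1D, and those named as higher include Asprv1 at 26.4 and 193 CPM.

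Gene lists fixed before the data were examined were then compared over all kept cells. All 11 measured genes of early B cell development had a ratio below 1, with a median log2 ratio of -2.42, lower than that of all 10000 random lists matched on expression. The 7 measured genes of MHC class II presentation were all lower, with a median of -1.42, among them Cd74, the invariant chain, 3.59-fold lower, and H2-Aa 2.77-fold lower. Plasma cell secretion genes had a median of -0.82 (percentile 0.005 of the random lists, 7 of 7 lower). Primary granule genes, which encode the proteases and peroxidase of the earliest neutrophil granules, had a median of 0.40 (percentile 99.9, 7 of 8 higher). Tertiary granule and mature neutrophil genes had a median of 0.23 (percentile 99.4, 9 of 12 higher). The glucocorticoid response list stood at 0.26 (percentile 99.4, 5 of 8 higher) and the insulin and FOXO list at 0.18 (percentile 99.5, 7 of 10 higher). The list of G2 and M phase genes stood at -0.27 (percentile 0.97, 18 of 18 lower), and the extracellular matrix and fibrosis list at -0.53 (percentile 0.385, 3 of 5 lower). The measured matrix genes include Col1a1 and Col1a2, of whose control counts 18 stromal or endothelial cells held 79.7% and 87.1%, so this list rests in part on few cells. These medians over all cells include the differences in cell shares given above.

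A group of lists was lower in T1D within nearly every class. Mitochondrially encoded genes, the transcripts of the respiratory chain read from the mitochondrial genome, had a median below 0 in 11 of the 11 classes compared, between -1.15 and -0.48, and lay at or under the 2.5th percentile of random lists in all 11. Over all cells mt-Nd2 was 2.71-fold lower (2.64 to 2.78). The list covers 7 measured protein-coding genes of 13, and the whole mitochondrial share of counts, ribosomal RNA of mitochondria included, was 3.07% in the control library and 2.87% in the T1D library. Unfolded protein response genes had a median below 0 in 11 classes, at or under that percentile in 10, and Hspa5, the main chaperone of the endoplasmic reticulum, was 2.24-fold lower over all cells (2.20 to 2.28). Heat shock genes had a median below 0 in 11 classes, at or under that percentile in 8, and Hsph1, a cytosolic chaperone of the HSP110 family, was 6.24-fold lower (5.68 to 6.87). Ribosomal protein genes were below 0 in 9 of the 11 classes, and stood at 0.20 in immature and 0.12 in mature neutrophils. Type I interferon response genes were below 0 in 10 classes, with a median of -0.61 over all cells, lowest in mature neutrophils at -1.12 and in monocytes at -1.06, and stood at 0.11 in granulocyte-monocyte progenitors. RNA freed from other cells was subtracted at 2 levels, set by hemoglobin genes or by the plasma cell genes Jchain and Igha, which gave different amounts, so no share of free RNA is settled here. At the hemoglobin level the medians in mature B cells turned to 2.31 for the unfolded protein response and 1.23 for heat shock, and the log2 ratio of Hspa5 there to 5.02. At the plasma cell level the 2 medians stood at -0.81 and -0.99, and Hspa5 stayed lower in T1D.

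Some single genes also went one way in all 11 classes. Cebpb passed the size rule above the control in 11 of 11. Its 44.4 and 127 CPM in T or NK cells and 52.3 and 145 CPM in mature B cells lay below the 71.8 and 226 CPM over all kept cells. Free RNA may thus give part of its values in these classes. H1f0 was higher in 11 and passed the rule in 6, and Cirbp, a cold-inducible RNA-binding protein, was higher in 11 and passed it in 6. Fkbp5, a co-chaperone induced by glucocorticoids, had a ratio above 1 in 11, with a counting interval above 1 in 10, and passed the rule in 7. In granulocyte-monocyte progenitors it stood at 70.9 and 74.9 CPM, with an interval of the ratio of 0.89 to 1.26. In immature neutrophils it lay at a log2 ratio of -0.12 with free RNA subtracted at the hemoglobin level and 0.64 at the plasma cell level. Ifi27l2a was lower in 11 classes and passed the rule in 6.

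**Figure D3:**
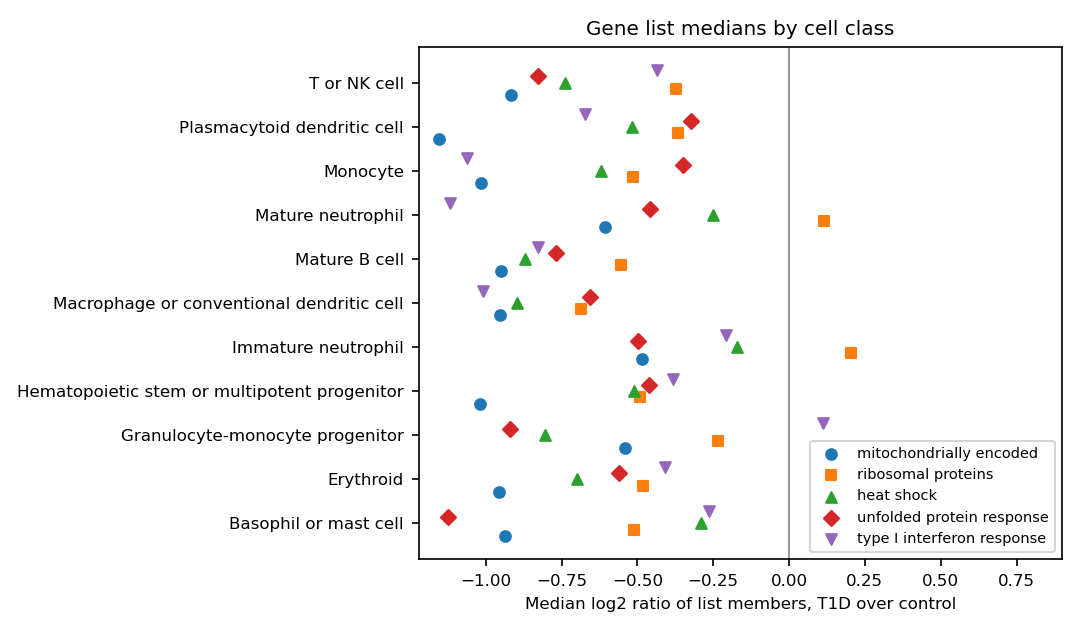
Median log2 ratio of T1D over control for the mitochondrially encoded, ribosomal protein, heat shock, unfolded protein response and type I interferon lists within each of 11 classes, with 1 point per list and class. Mitochondrially encoded genes lay below 0 in 11 of 11 classes and type I interferon response genes in 10 of 11.

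Mature neutrophils of the 2 libraries lay in different clusters. Of the control cells 91.2% were in a cluster led by Clec4d, Il1f9 and Acod1, and of the T1D cells 48.8% in a cluster led by Stfa2, Gm5483 and BC100530 and 45.2% in another led by Asprv1, Prok2 and Retnlg. The overlap of the libraries over these clusters was 14.8%. It was 54.1% over the clusters of cells thinned to 1000 counts, where the class held 2929 control and 5209 T1D cells. Within the class the stefin A genes were higher in T1D, Stfa2 11.2-fold (9.24 to 13.8), Stfa1 4.30-fold and Stfa3 4.63-fold, and BC100530 10.2-fold. Hilpda, a lipid droplet protein, was 5.79-fold higher, Asprv1 4.62-fold and Cd38, an enzyme that consumes NAD, 5.99-fold. Id2, an inhibitor of helix-loop-helix transcription factors, was 3.26-fold higher, and lay at a log2 ratio of -0.29 with free RNA subtracted at the hemoglobin level and 1.61 at the plasma cell level. Interferon-induced genes were lower: Ifi27l2a 21.8-fold (16.9 to 28.6), Ifit1bl2 5.62-fold and Ifi204 3.70-fold. All 12 measured members of the type I interferon list had a ratio below 1, among them Isg15, a ubiquitin-like modifier, at 34.6 and 11.9 CPM. Thbs1, a matrix glycoprotein also carried by platelets, was 3.60-fold lower (3.51 to 3.69), and Spp1, which encodes osteopontin, 5.94-fold lower. Jaml, an adhesion molecule, Klra17, a lectin-like receptor, and Nt5e, the 5'-nucleotidase CD73, were between 3.67-fold and 3.75-fold lower.

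Further lists differed between mature neutrophils of the 2 libraries. Primary granule genes had a median of 0.58 (5 of 6 higher, percentile 99.9), with the serine protease gene Prtn3 at 20.3 and 57.4 CPM, and G2 and M phase genes a median of 0.46 (6 of 8 higher), which turned to -0.30 with free RNA subtracted at the plasma cell level. MHC class I presentation genes had a median of -0.40 (6 of 9 lower), and immediate early genes, which respond within minutes to stress or cell dissociation, -0.46 (13 of 15 lower). Hemoglobin and heme genes, which belong to erythroid cells, stood at 0.88 here (5 of 5 higher). In control and T1D mature neutrophils hemoglobin genes reached 52.4% and 87.0% of their CPM over all kept cells, and plasma cell genes 3.82% and 6.41%. In the class 28 genes passed the size rule above the control and 42 below. The split was 22 and 54 with TMM scaling, 20 and 64 with DESeq2 scaling and 82 and 39 with ribosomal RNA left out of the totals. The last 2 moved the median of all genes by -0.10 and 0.16.

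Immature neutrophils lay in 3 clusters, and the one led by Fcnb and the cell cycle genes Ube2c and Cenpf held 1098 of 3516 control cells and 1853 of 4623 T1D cells, so the mix of stages differed. In this class H1f0 was 13.8-fold higher in T1D (11.8 to 16.2), Stfa1 12.4-fold, Asprv1 7.43-fold, Cd38 7.06-fold, Hilpda 5.13-fold, Cebpb 3.21-fold and Glul, glutamine synthetase, 2.97-fold. S phase genes had a median of 0.39 (12 of 14 higher), among them the replication helicase gene Mcm6 at 1.73-fold and Rrm2, a subunit of ribonucleotide reductase, at 1.56-fold. Primary granule genes stood at 0.45 (7 of 7 higher), with the myeloperoxidase gene Mpo 2.61-fold higher, and the list stood higher still in T or NK cells, at 0.95. The list of leukocyte trafficking chemokines and receptors had a median of 0.55 (4 of 5 higher). Among the genes lower in T1D were the interferon-induced Ifitm3 (2.67-fold), Oas3 (2.89-fold) and Ifi27 (2.67-fold), and the lysozyme gene Lyz2 (2.33-fold, 2.30 to 2.36). Rgs2, a regulator of G protein signalling, was 2.41-fold lower, Hspa5 stood at 404 and 184 CPM, and the myosin light chain gene Myl12a was 2.16-fold and Gapdh, a glycolytic enzyme, 2.06-fold lower. Glycolysis genes as a list stood at -0.20 (8 of 15 lower, percentile 0.72). Hba-a2, an alpha globin gene of erythroid cells, was 2.77-fold higher here, and hemoglobin and heme genes had a median of 1.47 (5 of 5 higher), at 17.9% and 45.2% of the CPM of hemoglobin over all cells, against 2.91% and 5.06% for plasma cell genes. With free RNA subtracted at the hemoglobin level, S phase turned to -0.074 and ribosomal proteins to -2.54, and at the plasma cell level they stood at 0.41 and 0.23. In all, 21 genes passed the size rule above the control and 11 below, against 18 and 17 with TMM scaling, 18 and 15 with DESeq2 scaling, and 41 and 9 with ribosomal RNA left out, which moved the median of all genes by 0.10.

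In monocytes NF-kB genes were higher in T1D. Saa3, an acute phase serum amyloid, had 48 control and 1681 T1D counts, 37.3-fold higher (28.0 to 50.8), and this class held 85.4% of the gene's counts in the T1D library. Il6, a cytokine, was 7.14-fold higher (5.45 to 9.48), but this class held 34.1% of its T1D counts, and over all kept cells it stood at 16.7 and 23.5 CPM. The NF-kB inflammatory list had a median of 0.90, above all 10000 random lists, with 10 of 13 members higher. Among them Il1b stood at 316 and 906 CPM, the NF-kB inhibitor gene Nfkbia at 287 and 815, and Nfkbiz at 167 and 405. The tertiary granule and mature neutrophil list stood at 0.77 (10 of 12 higher), with the formyl peptide receptor gene Fpr2 3.44-fold higher. Secondary granule genes stood at 0.48 (10 of 12 higher), with Chil3, a chitinase-like protein, 4.03-fold higher. These are neutrophil genes, the 2 lists lay in the highest 2.5% of random lists in 6 and 7 of the 11 classes, and in monocytes hemoglobin genes reached 19.1% and 56.9% of their CPM over all cells and plasma cell genes 1.79% and 3.91%. Primary granule genes stood at 0.51 (4 of 5 higher) and adipogenesis and lipid storage genes at 0.47 (4 of 5 higher), with the lipid droplet coat gene Plin2 2.24-fold higher. Cd38 was 37.2-fold higher (22.0 to 68.6) and Mt1, a metal-binding metallothionein, 6.18-fold. Shtn1 was 5.46-fold higher, and Zfp36l1, which promotes decay of AU-rich messages, 5.36-fold higher.

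All 14 measured type I interferon genes were lower in T1D monocytes. Ifi27l2a was 9.12-fold lower (7.95 to 10.5), and the interferon-induced Oas3, Ifi203, Slfn5 and Samd9l were between 2.83-fold and 3.57-fold lower. Cx3cr1, the fractalkine receptor of nonclassical monocytes, was 4.50-fold lower (3.71 to 5.49), Ass1, an enzyme of arginine synthesis, 3.89-fold, and Atf3, a stress-induced transcription factor, 2.71-fold. MHC class II genes had a median of -1.05 (6 of 6 lower), with Cd74 5.38-fold lower, and turned to 0.048 with free RNA subtracted at the hemoglobin level and stood at -1.08 at the plasma cell level. S phase genes stood at -0.49 (13 of 13 lower), and at 0.023 with at most 10% mitochondrial counts and 0.065 with the same lowest total, settings under which a cluster led by F13a1 that has no name here joined the class. Hemoglobin and heme genes had a median of 0.33 (7 of 10 higher). In all, 72 genes passed the size rule above the control and 51 below, against 88 and 29 with TMM scaling and 82 and 32 with DESeq2 scaling.

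Mature B cells of both libraries lay in the same 2 clusters, led by Ms4a1 and Ighd. Early B cell development genes were lower in T1D within the class too, with a median of -1.49 (9 of 9 lower), Vpreb3 6.51-fold lower (5.04 to 8.54) and Cd79a 2.90-fold lower. Rag1 had 75 control counts and none in T1D, and its 28.0 CPM in the control class lay next to the 28.2 CPM over all control cells, precursors included, so it is no evidence of a change within mature B cells. The B cell genes Fam129c and Cd72, a coreceptor of the B cell, were 18.2-fold and 10.9-fold lower, Akap12 37.8-fold (14.6 to 140) and the cyclin gene Ccnd2, which drives entry into the cell cycle, 10.7-fold lower. Cecr2 and Tifa, an adaptor of NF-kB signalling, were 15.9-fold and 12.3-fold lower. Vpreb3, Akap12 and Cecr2 also led a pro- or pre-B cluster that held control cells alone. Over 20 starts the mature B cell class held 833 to 1584 control cells and 540 to 544 T1D cells. A change within mature B cells is thus not separated from precursors at the border of the control class. Ifi27l2a was 10.7-fold lower at 92.7 and 8.63 CPM, next to 103 and 8.96 CPM over all kept cells. At the levels set by hemoglobin (65.2% in control, 18.5% in T1D) or plasma cell genes (3.58% and 8.88%), free RNA would give only part of these CPM. All 10 measured interferon genes were lower, with a median of -0.83. All 10 unfolded protein response genes and all 8 heat shock genes were lower, with Hspa5 2.35-fold lower and the mitochondrial chaperonin gene Hspe1 2.68-fold lower. Among the genes higher in T1D, Fkbp5 was 5.43-fold higher (3.98 to 7.50), Hilpda 7.14-fold and the phosphatase gene Ptpn22, which restrains antigen receptor signalling, 3.06-fold. Cebpb was 2.78-fold higher and Qsox1, a sulfhydryl oxidase, 2.51-fold.

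Asprv1, Olfm4 and Prok2 were also named as higher in mature B cells, at 6.27-fold, 3.81-fold and 3.50-fold, and are neutrophil genes in these libraries. Secondary granule genes had a median of 0.33 in the class (10 of 12 higher), and hemoglobin and heme genes -1.36 (5 of 7 lower). Hemoglobin genes reached 65.2% and 18.5% of their CPM over all cells in the control and T1D class, and plasma cell genes 3.58% and 8.88%. In all, 14 genes passed the size rule above the control and 105 below, and 72 and 122 with ribosomal RNA left out of the totals.

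As a class, T or NK cells had lower levels of genes of killing in T1D. The cytotoxicity list had a median of -1.14 (9 of 10 lower), below all 10000 random lists, with the chemokine gene Ccl5 2.45-fold, the perforin gene Prf1 2.69-fold and the granzyme gene Gzma 2.17-fold lower. Klra8, an activating receptor of NK cells, was 5.52-fold lower (4.02 to 7.70), and the chemokine genes Xcl1 and Ccl3 6.50-fold and 4.35-fold. Ncr1, an NK receptor, had 85 counts in 58 of the 513 control cells and 28 counts in 20 of the 718 T1D cells. Cd3e, a chain of the T cell receptor complex, had 279 counts in 183 control cells and 254 in 193 T1D cells, 153 and 118 CPM. The T cell genes Trac (178 and 122 CPM) and Cd8a (102 and 76.9 CPM) were lower too, and Cd4 stood at 21.4 and 22.2 CPM. The mix of T and NK cells may differ between the libraries, but this alone would not lower both Ncr1 and Cd3e. It is not separated here from lower levels within either type or from genes of other cells in the class. The glucocorticoid response list had a median of 0.50 (5 of 8 higher), above all 10000 random lists, with Txnip, an inhibitor of thioredoxin, 2.40-fold and Fkbp5 2.23-fold higher. Nuclear oxidative phosphorylation genes stood at -0.30 (14 of 18 lower), G2 and M phase genes at 0.26 (15 of 18 higher) and NF-kB inflammatory genes at -0.35 (10 of 14 lower). H1f0 was 11.3-fold higher (6.78 to 20.1), the actin-severing gelsolin gene Gsn 2.65-fold, Plin2 2.59-fold, and Cebpb, Mapk13, a stress-activated kinase, and Tmem176b between 2.87-fold and 3.16-fold higher. Hsph1 was 6.63-fold lower.

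Genes of other classes also differed in T or NK cells. The B lineage genes Vpreb3 (132 control counts and none in T1D, at least 52.0-fold lower), Ebf1 (33.7-fold), Cd79b (8.72-fold) and Ighm (3.92-fold) were lower, with early B cell development genes at -2.54 and MHC class II genes at -1.46. Vcan, a monocyte gene in these libraries, and Fcnb, a gene of immature neutrophils, were 4.33-fold and 3.94-fold higher. Primary granule genes stood at 0.95 (5 of 6 higher) and secondary granule genes at 0.56 (11 of 12 higher). Hemoglobin genes reached 42.7% and 44.1% of their CPM over all cells here, and plasma cell genes 4.67% and 7.65%. In all, 36 genes passed the size rule above the control and 57 below, against 66 and 87 with ribosomal RNA left out and 63 and 94 after thinning.

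In granulocyte-monocyte progenitors H1f0 (7.18-fold), Cirbp (19.3 and 77.1 CPM) and Glul (3.59-fold) were higher in T1D. The chaperone genes Hsph1 (6.77-fold), Hspa5 (3.09-fold, 2.97 to 3.21) and Creld2 (3.11-fold) were lower. All 10 measured unfolded protein response genes and all 8 heat shock genes had a ratio below 1 there, with medians of -0.92 and -0.80. Hemoglobin genes reached 3.99% and 27.3% of their CPM over all cells there, and plasma cell genes 1.27% and 2.47%. All 7 measured NF-kB inflammatory genes had a ratio above 1, with a median of 0.56, Il1b at 1.88-fold, Nfkbia at 1.74-fold and Ptgs2, the inducible cyclooxygenase, at 1.63-fold. With free RNA subtracted at the hemoglobin level that median turned to -3.27, Il1b to -3.27 and Ptgs2 to -1.48, and at the plasma cell level they stood at 0.56, 0.77 and 0.56.

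In macrophages or conventional dendritic cells, Cd5l, a secreted scavenger protein of tissue macrophages, was 11.4-fold higher in T1D (7.78 to 17.1). Adipogenesis and lipid storage genes had a median of 1.10 (6 of 8 higher), above all 10000 random lists, with the fatty acid binding protein gene Fabp4, which also led the stromal cluster, 4.11-fold and Plin2 2.30-fold higher. Hemoglobin genes reached 55.1% and 82.4% of their CPM over all cells in this class, and plasma cell genes 1.87% and 4.84%. Type I interferon genes had a median of -1.01 (13 of 14 lower), with Ifi27l2a 5.50-fold and Oasl2 3.35-fold lower, and the viral RNA sensor gene Ddx58 was 10.2-fold lower. Cd209a, a lectin of monocyte-derived dendritic cells, was 6.85-fold lower (4.72 to 10.3). Cd5l was found in 11 of 325 control cells and 35 of 232 T1D cells of the class. Over 20 starts the class held 52 to 1084 control cells and 56 to 299 T1D cells. A different mix of macrophages and dendritic cells is thus not separated from a change within either type. Asprv1 and Prok2 were 7.83-fold and 5.71-fold higher, and Prok2 lay at a log2 ratio of -0.37 with free RNA subtracted at the hemoglobin level and 2.21 at the plasma cell level.

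Plasmacytoid dendritic cells had higher levels of the chemokine gene Ccl9 (4.96-fold), H1f0 (4.21-fold) and Id2 (4.14-fold) in T1D. Havcr1 (9.48-fold, 3.19 to 46.5) and the nonclassical MHC gene H2-Q7 (6.47-fold) were lower. So was the B cell gene Cd79b, whose 105 and 13.5 CPM lay next to the 114 and 14.4 CPM over all kept cells, while hemoglobin genes reached 41.4% and 56.2% of theirs and plasma cell genes 2.52% and 2.73%. In erythroid cells H1f0 (7.55-fold), the membrane metalloprotease gene Mmp14 (2.79-fold) and the cell cycle inhibitor gene Cdkn1a (2.66-fold) were higher, and the desaturase gene Scd2 (5.21-fold), Hsph1 (3.94-fold) and the tubulin cofactor gene Tbca (2.79-fold) lower. After thinning to 1000 counts per cell Cdkn1a lay at a log2 ratio of -0.083 and the type I interferon median of erythroid cells turned from -0.41 to 0.11. In stem or multipotent progenitors Hsph1 (5.17-fold), the dynein light chain gene Dynll1 (4.15-fold) and Zfp664 (3.22-fold) were lower. Prg2, a granule protein of eosinophils, was 74.9-fold higher there, Ighg2c 146-fold with 2 control counts (39.9 to 1210), and the beta globin gene Hbb-bt 17.4-fold, all 3 genes of other cell types. In basophils or mast cells Olfm4, a neutrophil gene here, was 19.9-fold and F10, coagulation factor X, 13.6-fold higher. Tdrd5 was at least 14.2-fold higher, with no control counts. Secondary granule genes stood at 0.43 (11 of 12 higher) in this class. Hemoglobin genes reached 27.6% and 10.2% of their CPM over all cells, and plasma cell genes, going the other way, 1.19% and 27.7%. Prg2 was 7.52-fold lower, the eosinophil peroxidase gene Epx at least 18.4-fold lower with no T1D counts, and the mitotic checkpoint gene Mad2l1 11.8-fold lower. Of the basophils 3 of 152 control cells held all of the Prg2 counts of the class, and 1 cell held 1126 of 1380, so the eosinophil values of this class rest on few cells.

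The bone-related genes came from few cells. The stromal or endothelial cluster, led by the collagen genes Col1a2 and Col1a1, held 18 control and 13 T1D cells, too few to compare as a class. Over all kept cells Col1a1, the main collagen of bone matrix, had 2253 control and 55 T1D counts, and 1 control cell held 892 of them. Bglap, which encodes osteocalcin, had 489 counts in 43 control cells, of which 1 cell held 328, and none in T1D. Spp1 had 1222 and 746 counts, of which the stromal cluster held 40 and 395, with 240 in 1 T1D cell, and the osteoblast transcription factor gene Runx2, which also led the plasmacytoid dendritic cell cluster, 3819 and 1759. Cxcl12, the chemokine that retains stem cells in the marrow, had 597 and 359 counts, of which the stromal cluster held 92.5% and 88.9%. Tnfsf11, the osteoclast-inducing ligand RANKL, had 13 and 6 counts, and its decoy receptor gene Tnfrsf11b 3 and 1. Among macrophages or dendritic cells the osteoclast differentiation list stood at -0.14 (6 of 9 lower, percentile 26.3) and at 0.18 after thinning. In that class Ctsk, the collagen-degrading protease of osteoclasts, was 17.2-fold lower (5.70 to 84.6), with 98 control counts in 2 cells and 3 T1D counts. Acp5, the tartrate-resistant acid phosphatase, was 2.45-fold lower (1.69 to 3.63), with 163 and 35 counts. No difference within osteoblasts or osteoclasts could be read at this number of cells.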

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

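The tests chosen only after the result was seen are those of placement in other clusters and of glucocorticoids for B cell precursors, of the interferon shift and of depth for mature neutrophils, and of ribosomal RNA for both chaperone lists.

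The barcodes that the filters removed belong to no comparison above, and were 1.22% of the T1D barcodes (192 of 15771) against 0.598% of the control barcodes (77 of 12880). Their median share of nuclear ribosomal RNA was 74.5% in T1D and 25.8% in control. A cluster led by ribosomal RNA and eosinophil granule genes, left unnamed, held 3.40% of kept T1D cells (530) and 0.281% of kept control cells (36). Among cells at or above the lowest total of the control library it held 1.71% of T1D cells (207 of 12109).

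No cluster of B cell precursors held T1D cells. Lower depth is argued against, since 139 control cells still carried at least 2 of Vpreb1, Igll1, Dntt, Rag1 and Rag2 after thinning to 1000 counts, against 0 T1D cells. Placement of such cells in other clusters is argued against too, with 1 T1D cell of any cluster carrying at least 2 of these genes. Exposure to glucocorticoids, which are known to deplete B cell precursors, may have a part: the glucocorticoid list lay in the highest 2.5% of random lists in 5 of 11 classes, with a median of 0.27 over the classes. Exposure asked for at least 9 classes and its absence for a median of 0 or less, so the test leaves it open. The diabetic state, the streptozotocin itself and a difference between animals or preparations stay open and untested, since each group is 1 library.

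Mature neutrophils of the 2 libraries fell in different clusters. Lower depth of the T1D library is a candidate explanation of part of this split: when cells were thinned to 1000 counts before clustering, the overlap of the libraries over clusters rose from 14.8% to 54.1%, past the 50% that depth asked for. Part of the split stayed: clusters led by Prok2 and by Stfa2 held 35.2% and 18.6% of T1D cells against 5.80% and 2.01% of control cells. Thinning also blurs clusters, and it changed which cells were named mature neutrophils, from 2250 control and 4604 T1D cells to 2929 and 5209. The test does not separate either of these from equal depth. A shift of interferon genes alike in every cell is argued against only for the list as a whole. Its lower quartile was no lower than -0.73 in granulocyte-monocyte and in stem or multipotent progenitors, above the median of -1.12 in mature neutrophils. In granulocyte-monocyte progenitors 5 of 6 measured members had a ratio above 1, but in stem or multipotent progenitors 8 of 12 had a ratio below 1. The 5 CPM added draws weakly expressed members toward 0, and Ifi27l2a was lower in all 11 classes. A shift shared by some of these genes thus stays open. Free RNA from other cells could account for part of the 28 higher genes, since the median ratio of their CPM there to that in T1D T or NK cells was 1.75 (quartiles 0.74 to 4.12), between the 1.5 and 3 set beforehand. A state of neutrophils in diabetes, the toxicity of streptozotocin and a difference between animals stay open and untested.

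Heat shock and unfolded protein response genes were lower in T1D across classes. The larger share of ribosomal RNA is argued against, since the median of the heat shock list over 11 classes was -0.56 with ribosomal RNA left out and -0.62 with it, and that of the unfolded protein response -0.50 and -0.56. A colder or shorter preparation of the T1D cells is a candidate explanation: Rbm3, which is induced by cold, was higher in 10 of 11 classes, with a median log2 ratio of 0.50, and Cirbp, whose rise had prompted the test, in 11. Immediate early genes, which a shorter digestion would also lower, had medians below 0 in 6 of the 11 classes. The preparation went with the group, so a response to diabetes stays open and untested.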

How the results depend on the processing

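Alternatives chosen only after results were seen are the same lowest total, removal of the highest Scrublet scores, the mixed cluster counted as B cells, totals without ribosomal RNA, the best-agreeing start and free RNA subtracted at the plasma cell level. No paired analysis was possible because each group has 1 library and no animal joins them. The doublet caller marked almost no cell, so no cell was removed and the effect of doublets on the values is unknown. Of the shares under alternatives, 117 stayed within the counting interval of the value above, 55 left it and 8 changed sign where that interval had excluded no difference. Of the list medians, 1538 stayed within 0.2 and 202 went further, and 10 changed sign among lists in the outer 2.5% of random lists on either side; a list nearer the middle was not counted as changing sign. Of the values of single genes, 2123 stayed within the counting interval, 929 left it and 17 changed sign.

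The log2 ratio of a share of cells left its interval as follows. With at most 10% mitochondrial counts it was -2.50 for the B lineage, 0.67 for erythroid cells, 0.035 for stem or multipotent progenitors, 0.038 for macrophages or dendritic cells and -1.91 for mature B cells. There too it was -2.26 for plasmacytoid dendritic cells and -8.13 or lower for pro- or pre-B cells. With the control library's lowest total in both libraries it was -2.77 for the B lineage, 0.28 for the neutrophil lineage, -0.14 for erythroid cells, -0.092 for stem or multipotent progenitors and 0.58 for immature neutrophils. There too it was -1.27 for macrophages or dendritic cells, -1.67 for mature B cells, -0.095 for mature neutrophils, 0.35 for monocytes and -8.58 or lower for pro- or pre-B cells. With each library clustered alone it was -2.16 for the B lineage, -0.83 for stem or multipotent progenitors, 0.41 for immature neutrophils, 4.56 or higher for macrophages or dendritic cells and -1.36 for mature B cells. There too it was 0.33 for mature neutrophils, 0.22 for monocytes, -7.66 or lower for plasmacytoid dendritic cells and -8.61 or lower for pro- or pre-B cells. Over cells neither neutrophil nor erythroid it was -1.92 for the B lineage, -0.055 for basophils or mast cells, 1.38 for granulocyte-monocyte progenitors, 0.016 for stem or multipotent progenitors and -0.34 for macrophages or dendritic cells. There too it was -0.47 for mature B cells, 0.40 for monocytes, -2.15 for plasmacytoid dendritic cells, -8.76 or lower for pro- or pre-B cells and 0.63 for T or NK cells. With 50 principal components it was 1.00 for erythroid cells, -0.13 for stem or multipotent progenitors, 0.21 for immature neutrophils, -1.84 for mature B cells and 0.52 for mature neutrophils. There too it was -8.12 or lower for pro- or pre-B cells. Without the 6% of cells of highest Scrublet score it was 0.44 for granulocyte-monocyte progenitors, -1.88 for mature B cells, 0.57 for mature neutrophils, -2.15 for plasmacytoid dendritic cells and -7.91 or lower for pro- or pre-B cells. With cells thinned to 1000 counts before clustering it was 0.76 for granulocyte-monocyte progenitors, 0.20 for immature neutrophils, -1.89 for mature B cells, 0.55 for mature neutrophils and -8.12 or lower for pro- or pre-B cells. At Leiden resolution 2 it was -0.22 for immature neutrophils, -1.43 for macrophages or dendritic cells, -1.26 for mature B cells and 0.97 for mature neutrophils. In the best-agreeing of 20 starts it was -1.21 for macrophages or dendritic cells, -1.26 for mature B cells and 0.55 for mature neutrophils. With the mixed B cell and monocyte cluster counted in it was -1.08 for mature B cells. With at least 500 genes per cell it was 0.62 for mature neutrophils and -2.10 for plasmacytoid dendritic cells. At Leiden resolution 0.5 it was -2.12 for plasmacytoid dendritic cells. Values marked as or lower, or as or higher, are bounds with 3 cells set for a library that had none. The erythroid values above 0 came where a cluster led by Prg2 or ribosomal RNA took the erythroid name. The values of macrophages or dendritic cells and of plasmacytoid dendritic cells with each library alone came where the class was not resolved in 1 library. For the other moves the cause was not tested.

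The number of genes past the size rule, with those higher and lower, left the range of 1.5-fold around the number above as follows. With 20 CPM added there were 58 (14 and 44) in all kept cells, 19 (14 and 5) in immature neutrophils, 71 (9 and 62) in mature B cells, 38 (16 and 22) in mature neutrophils, 73 (48 and 25) in monocytes and 51 (17 and 34) in T or NK cells. Without a CPM minimum there were 207 (45 and 162) in all kept cells, 71 (43 and 28) in immature neutrophils, 385 (92 and 293) in mature B cells, 168 (81 and 87) in mature neutrophils, 262 (135 and 127) in monocytes and 303 (126 and 177) in T or NK cells. At a minimum of 200 CPM there were 20 (4 and 16) in all kept cells, 8 (2 and 6) in immature neutrophils, 29 (3 and 26) in mature B cells, 18 (7 and 11) in mature neutrophils, 50 (26 and 24) in monocytes and 18 (5 and 13) in T or NK cells. At 1.5-fold there were 315 (90 and 225) in all kept cells, 160 (97 and 63) in immature neutrophils, 512 (133 and 379) in mature B cells, 307 (121 and 186) in mature neutrophils, 439 (158 and 281) in monocytes and 400 (165 and 235) in T or NK cells. Without ribosomal RNA there were 50 (41 and 9) in immature neutrophils, 194 (72 and 122) in mature B cells, 121 (82 and 39) in mature neutrophils and 153 (66 and 87) in T or NK cells. After thinning to 1000 counts there were 181 (29 and 152) in mature B cells and 157 (63 and 94) in T or NK cells. At Leiden resolution 2 there were 193 (41 and 152) in mature B cells. With the same lowest total there were 305 (92 and 213) in mature B cells. In the best-agreeing start there were 190 (41 and 149) in mature B cells. By its 2-fold threshold the rule has little reach for small changes. On counts simulated with counting error alone it recovered 0 of 50 genes changed 1.5-fold and 12 of 50 changed 2-fold.

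These single values changed direction, as log2 ratios. With TMM scaling S100a9 over all kept cells lay at 0.064 and Ighg2c over all kept cells lay at 0.085. With DESeq2 scaling S100a9 over all kept cells lay at 0.034 and Ighg2c over all kept cells lay at 0.057. Without ribosomal RNA S100a9 over all kept cells lay at 0.018 and Ighg2c over all kept cells lay at 0.043. After thinning Ighg2b over all kept cells lay at 0.44, Ighg2c over all kept cells lay at 0.77, Cdkn1a in erythroid cells lay at -0.083 and type I interferon response genes in erythroid cells lay at 0.11. With the same lowest total Ighg2c over all kept cells lay at 0.040 and S phase genes in monocytes lay at 0.065. Without the highest Scrublet scores Prg2 over all kept cells lay at 1.19. With free RNA subtracted at the hemoglobin level Il1b in granulocyte-monocyte progenitors lay at -3.27, Ptgs2 in granulocyte-monocyte progenitors lay at -1.48, NF-kB inflammatory genes in granulocyte-monocyte progenitors lay at -3.27 and Fkbp5 in immature neutrophils lay at -0.12. There too ribosomal proteins in immature neutrophils lay at -2.54, S phase genes in immature neutrophils lay at -0.074, Prok2 in macrophages or dendritic cells lay at -0.37 and Hspa5 in mature B cells lay at 5.02. There too unfolded protein response genes in mature B cells lay at 2.31, heat shock genes in mature B cells lay at 1.23, Id2 in mature neutrophils lay at -0.29 and MHC class II presentation genes in monocytes lay at 0.048. With free RNA subtracted at the level of plasma cell genes G2 and M phase genes in mature neutrophils lay at -0.30. With at most 10% mitochondrial counts S phase genes in monocytes lay at 0.023.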

Other observations

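No test was made for the values in this part, and the immunoglobulin and eosinophil genes were chosen only after their values were seen.

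Among immunoglobulin heavy chain genes Ighm had 52102 control and 11547 T1D counts, 909 and 223 CPM. Igha had 77371 control and 51908 T1D counts, Ighg2b 2702 and 2197, and Ighg2c 5112 and 4470. Ighg3 had 31 and 643 counts, of which 1 T1D cell held 603. The directions of Ighg2b and Ighg2c changed under other settings. Plasma cells held 75436 of the control counts of Igha and 48424 of its T1D counts.

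Several lists tied to diabetes lay near no difference over all kept cells. Glycolysis genes had a median log2 ratio of -0.068 (percentile 59.4, 10 of 16 lower), with Ldha, lactate dehydrogenase, at 308 and 384 CPM. NADPH oxidase genes stood at -0.068 (percentile 48.7), hypoxia genes at 0.059 (percentile 94.4) and p53 and DNA damage genes at -0.061 (percentile 62.0). Oxidative stress and NRF2 genes stood at -0.14 (percentile 24.8, 11 of 13 lower), while the heme oxygenase gene Hmox1 was 1.57-fold higher (1.48 to 1.66). The list of S100 alarmins and their receptors stood at -0.14 (percentile 32.8, 5 of 8 lower). In it S100a8 was 1.39-fold lower and S100a10 2.35-fold lower, and S100a9, at a log2 ratio of -0.071, turned above 0 with TMM scaling, DESeq2 scaling or ribosomal RNA left out.

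Eosinophils formed no named class. Their granule genes Prg2 and Epx had 2013 and 1232 counts, and 117 and 43, over all kept cells, and the log2 ratio of Prg2 turned from -0.48 to 1.19 without the cells of highest Scrublet score. The control cell with most Prg2 held 1126 of its counts, and the control cell with most Epx held 69.

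Niche factors of the stroma came from few cells. Kitl, the ligand of the stem cell receptor Kit, had 59 counts in each library, and the leptin receptor gene Lepr, which marks stromal cells around sinusoids, 34 and 62.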
